A study of Homo sapiens with 6 samples.

How the data were processed

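Total RNA of U87MG cells was sequenced in 6 libraries, 3 with a control hairpin and 3 with a hairpin against CREPT. Per the labels' protocols, RNA came from a column kit and libraries were made with NEBNext Ultra reagents. The labels do not say whether this library type keeps the strand. Whether a gene and its antisense partner were told apart is therefore unknown, which bears on the 95 antisense genes listed. Per the submitters' processing notes, HISAT2, HTSeq and the genome build GRCh38 were used, with no version or role given. How the authors normalized the values is not given in the sources used here.

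The data are 1 deposited table of 1630 genes. Its per-library signal values are, per the file headers, normalized expression values that the authors wrote with 2 decimals; the headers do not say whether they are TPM or FPKM, and they are treated here as a linear signal with an unknown depth. Low values, pooled over the genes of a library, took 28 to 29 of the 29 possible hundredths from 0.01 to 0.29, so no step of a single read was visible. If the values are scaled by gene length, each gene has its own step, and this check could not have shown one. Whole reads were not recovered and no test on counts was run. The table also holds, per the file headers, the authors' fold change as a ratio, its log2 value, a p-value and an adjusted p-value, and a mark of significance. Every listed gene carries the mark, the smallest absolute log2 fold change the authors list is 1.0009 and the largest adjusted p-value is 0.0497, so the table holds genes past a threshold on both and no unchanged genes for comparison. In 3 genes, CHURC1-FNTB, SLC15A2 and ENSG00000257390, the ratio of the mean values goes against the fold in the authors' deposited table; they were named after their values were seen. Over 721 genes with a group mean above 5, the log2 ratio of the means differed from the log2 fold in the authors' deposited table by a median of −0.017, and by over 0.5 in 17 genes.

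The design fixed before the data were examined assumed a table of all genes. It was kept as written, but each test was then run on a selected table. Values were transformed as log2(value + 1), genes with a value of at least 1 in at least 3 libraries were kept (1184 tested, 446 left out), and groups were compared with limma 3.58.1 in R 4.3.3 (no trend, no robust option, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. A change on this scale understates the change of low genes, so linear ratios of group means are given too. Gene lists (19) and marker lists (10) were fixed beforehand; a list with at least 5 tested members was tested with camera at a preset inter-gene correlation of 0.01, which 5 lists and 0 marker lists reached. Camera sets a list against the other genes of the selected table, not against the genome. Genes to be named were fixed by rule: the target first; the 10 largest rises and 10 largest falls among genes past the threshold with no overlap of groups, a mean in the higher group at or above the median of 5.223 and a protein-coding type of symbol; and up to 4 members past the threshold with the smallest adjusted p from each list. Genes named outside that rule are said to be so.

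Coordinates and gene types came from GENCODE v29 on GRCh38, where 1549 of the 1630 identifiers matched and 81 did not. The duplicate check found that any 2 libraries differed in at least 96.0% of genes, so none was counted as a repeat. The limma step was tested on simulated values for 1184 genes with the spread of the real ones: it recovered 41.2% of genes changed by 0.5 on the log2 scale, 87.7% of those changed by 1 and 97% of those changed by 2, and called 0.51% of unchanged genes. In that simulation 984 genes were unchanged and the spreads were shuffled between genes. The selected table holds no unchanged genes, so these shares check the step and do not carry over to that table. Other analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.

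Alternatives were a pseudocount of 0.1 or 5, no filter, a minimum of 10 in 3 libraries, median-of-ratios rescaling, quantile normalization, limma with trend and robust options, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Fisher's exact test of list directions was added after the data were seen. RPRD1B has no row and was not analysed here. Some of the gene families compared after the data were seen are not reported here.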

Results

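RNA was sequenced from U87MG cells, an established human glioblastoma line, in 2 groups. One group of 3 libraries carried a control short hairpin RNA (shControl) and the other group of 3 libraries carried a hairpin against CREPT (shCREPT). CREPT is the protein product of RPRD1B, which binds the C-terminal domain of RNA polymerase II. The series title places the work in glioblastoma and links CREPT to proliferation and to an immunosuppressive microenvironment, so the comparison asks which transcripts differ once CREPT is targeted. The table used here lists 1630 genes, each marked significant by the authors, with 1 normalized value per library. The authors marked 657 of them up and 973 down in shCREPT. The number of reads behind each library is unknown. The listed values summed to between 31893.69 and 33330.8 per library, and that sum covers the listed genes alone.

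The table holds no row for RPRD1B, so the level of the targeted gene was not analysed here and the knockdown was not checked. Only genes past the authors' threshold have a row, so nothing here shows a fall of the RPRD1B transcript. Whether RPRD1B missed that threshold or was left out for another reason is unknown. None of the 17 fixed partners of CREPT at the polymerase, such as RPRD1A, POLR2A and CDK9, has a row either. The libraries of a group resembled each other more than those of the other group over the listed genes, with Pearson's r of 0.983 to 0.989 within groups and 0.809 to 0.841 between them. These correlations are across genes that had been selected for a difference, and genes are not independent replicates.

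In shCREPT cells the chemokines CCL3 and CCL3L3, the cytokine IL11, the chromatin protein HMGA1 and the transcription factor MYC rose, while the matrix proteoglycan BGN, the astrocyte filament protein GFAP and the calcineurin regulator RCAN1 fell. CCL3, a chemoattractant of monocytes and T cells, went from 0.24 ± 0.113 to 25.6 ± 1.13 (SD, n = 3). IL11 rose 11.4-fold, from 19.7 ± 1.51 to 225 ± 1.18, and HMGA1 rose 5.84-fold, from 45.1 ± 2.82 to 264 ± 33.1. BGN fell from 102 ± 13.9 to 1.42 ± 0.14, a level 72.1-fold lower, and GFAP fell from 434 ± 13.5 to 45.5 ± 3.75, a level 9.53-fold lower (SD, n = 3 throughout). All 13 listed genes of the G1/S, G2/M and DNA repair lists rose, and the listed genes fell for hypoxia and glycolysis (8 of 8, with BNIP3L turning sign under median-of-ratios rescaling), lipid synthesis (4 of 4) and the unfolded protein response (4 of 4, of which HSP90B1, CRELD2 and VLDLR lost their call under that rescaling). Most members of each of these lists have no row, and 59.7% of all listed genes were marked down. Of these lists only G1/S and hypoxia had enough members for a list test, which G1/S passed (camera adjusted p = 0.00903; adjusted p = 0.253 with an estimated correlation) and hypoxia did not (camera adjusted p = 0.0648).

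**Figure D1:**
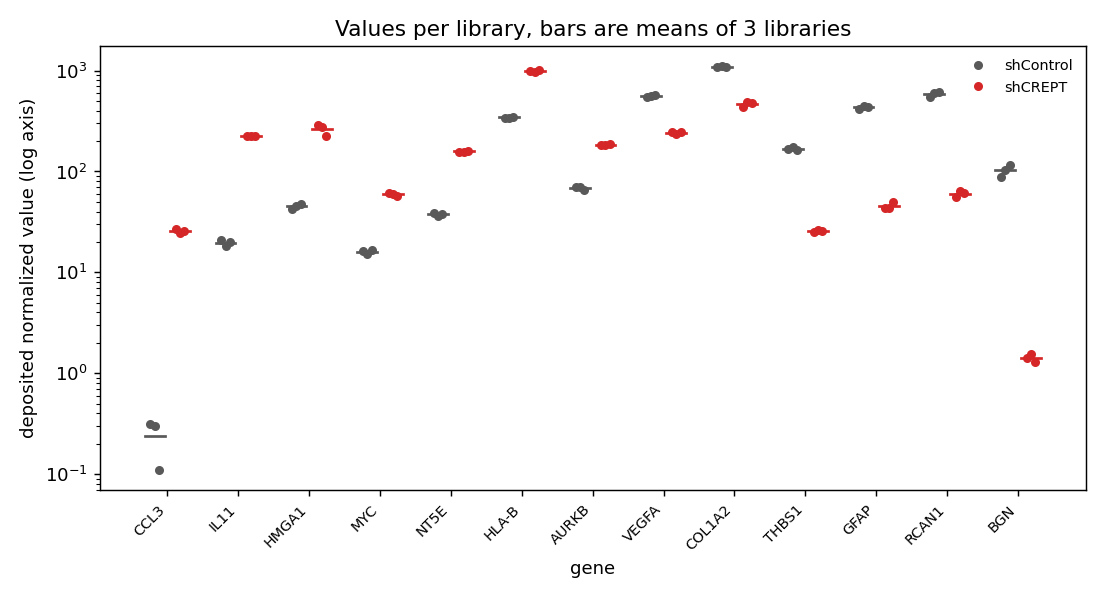
Deposited normalized value of 13 named genes in each of the 6 libraries, on a log axis, with grey points for shControl, red points for shCREPT and horizontal bars for the mean of 3 libraries. The groups do not overlap for any gene drawn; CCL3 lies between 0.11 and 0.31 in shControl and between 24.56 and 26.81 in shCREPT, and BGN lies between 87.97 and 115.63 in shControl and between 1.28 and 1.56 in shCREPT.

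With limma and Benjamini-Hochberg adjustment on log2(value + 1), 1159 of 1184 tested genes passed an adjusted p of 0.05, 481 higher (41.5%) and 678 lower (58.5%) in shCREPT. By 1 or more on the log2 scale, 305 were higher and 425 lower. That majority turned under median-of-ratios rescaling (476 higher, 92 lower) and quantile normalization (416 higher, 276 lower). Every tested gene had been picked by the authors for this same difference, so the counts describe a selected table and not how many genes of the cell changed. In 1146 of the tested genes the groups did not overlap. Chance alone gives 10% of genes without such a selection, so the excess here is no separate evidence. The median log2 change over the tested genes was −0.76; a median-of-ratios rescaling over these genes, which sets the typical listed gene near no change, moved it to −0.12 and gave 492 higher (57%) and 371 lower (43%), and quantile normalization moved it to −0.52. The rescaling raises every gene in shCREPT against shControl by 0.89 on the log2 scale before the pseudocount, so each fall printed here is smaller under it and each rise larger. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical, and a permutation test of 3 against 3 could not go below an exact two-sided p of 0.1.

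Among the 10 largest rises, CCL3L3 had the largest log2 change, 5.50 ± 0.18 (SE), followed by CCL3 with 4.43 ± 0.10 and IL11 with 3.45 ± 0.09 (limma adjusted p = 2.34e-06, 1.01e-06 and 1.39e-06). CCL3 (chromosome 17, 36088256 to 36090169, GRCh38) and CCL3L3 (chromosome 17, 36194869 to 36196758) are near-identical copies, so how reads were divided between them is uncertain. The other rises among these 10 were HHLA1, CLDN4, LRRK1, PI3, SEMA7A, ZBTB32 and HMGA1, with log2 changes of 2.06 to 2.62. CLDN4, a tight junction protein, went from 2.85 ± 0.484 to 21.6 ± 1.15, and the semaphorin SEMA7A from 7.38 ± 1.29 to 34.9 ± 1.97 (SD, n = 3). PI3, an elastase inhibitor, had shCREPT values of 17.3, 9.81 and 19.42.

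The largest fall was that of BGN (biglycan; chromosome X, 153494939 to 153509554, GRCh38), with a log2 change of −5.41 ± 0.12 (SE; limma adjusted p = 1.01e-06). GPM6B, a neural membrane glycoprotein, and SLC38A3, a glutamine transporter, had log2 changes of −3.77 ± 0.08 and −3.69 ± 0.15. RCAN1 fell from 588 ± 36.4 to 60.2 ± 3.96 (SD, n = 3), and the small heat shock protein CRYAB from 49.7 ± 3.24 to 4.81 ± 0.361. HAS2, which makes hyaluronan, fell from 13.4 ± 0.597 to 0.81 ± 0.115. SCUBE3, PLEKHS1 and EHF completed the 10 largest falls, with log2 changes of −2.85 to −3.21.

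The question raised by the word proliferation in the title bears on the cell cycle lists. Of the 30 genes fixed for G1/S and DNA replication, 6 had a row and all 6 rose, namely UHRF1, E2F1, CDC6, CCNA2, MCM4 and CDT1, while the other 24 have no row in the table. MCM4 and CDT1 were named after their values were seen. The list moved up against the rest of the table (camera with a preset correlation of 0.01, adjusted p = 0.00903 over 5 lists), and this call was lost with an estimated correlation (adjusted p = 0.253 with an estimated correlation). UHRF1, which keeps DNA methylation through replication, went from 36.1 ± 1.28 to 84.2 ± 2.08, and the transcription factor E2F1 from 12.8 ± 0.444 to 27.0 ± 0.745 (SD, n = 3). Of 27 G2/M genes, 3 had a row and rose, the mitotic kinases AURKB (2.68-fold) and PLK1 (2.15-fold) and the transcription factor FOXM1 (2.07-fold). Of 30 DNA repair genes, 4 had a row and rose, XRCC2, EXO1, BRCA1 (2.37-fold) and RAD54L. The p53 list held 1 rise, GADD45A (2.33-fold), and 1 fall, TP53INP1 (2.45-fold lower). MYC, which stands in both the Wnt list and the MYC list, rose 3.71-fold from 16.0 ± 0.792 to 59.5 ± 1.72 (SD, n = 3) and was the 1 listed gene of 29 in the MYC list. In the Wnt list FOSL1 rose 2.99-fold and TNFRSF19 was 5.03-fold lower.

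The title's immune terms bear on the next lists. Of 38 chemokines and myeloid cytokines, 11 had a row and 9 were tested: CCL3, IL11, CX3CL1, CCL4, CXCL8 and CXCL16 rose, and CSF1, CXCL10 and CXCL9 fell. The 2 too low to be tested are CSF2, up in the authors' deposited table with a log2 fold change of 5.51, and IL33, down in it with −4.54. CX3CL1, the ligand of the monocyte receptor CX3CR1, rose 3.26-fold to 77.2 ± 0.957, CXCL8 rose 2.07-fold to 10.5 ± 0.824, and CSF1, a growth factor of macrophages, fell from 170 ± 12.9 to 83.5 ± 1.63 (SD, n = 3). CXCL10, a ligand of the T cell receptor CXCR3, was 2.12-fold lower at 266 ± 20.7. The list as a whole did not pass (camera adjusted p = 0.0819). Under median-of-ratios rescaling CSF1 kept its sign and lost its call, with a log2 change of −0.14 (limma adjusted p = 0.188, the highest over its alternatives). Of the 27 immunosuppressive ligands and enzymes, 7 had a row, and the 6 tested were split into 3 rises and 3 falls (camera adjusted p = 0.559): NT5E, the surface enzyme that makes adenosine, rose 4.19-fold to 158 ± 1.26, GDF15 rose 3.25-fold, LGALS9 rose 2.05-fold, and VEGFA, TGFB3 and PTGS2 fell, while the untested PTGES is up in the authors' deposited table with a log2 fold change of 2.56. Of 23 antigen presentation genes, 4 had a row. The 3 tested rose, HLA-B from 344 ± 4.85 to 982 ± 22.3, HLA-C from 363 ± 9.53 to 776 ± 5.29 and HLA-F from 45.4 ± 5.08 to 88.7 ± 6.46; HLA class I genes are similar in sequence and can share reads. The remaining member, CD74, the class II invariant chain, was too low to be tested and is down in the authors' deposited table, with a log2 fold change of −1.96. From the interferon list MX2 (1.98-fold) and XAF1 (2.14-fold) rose, and the other 34 members have no row. In the NF-kappaB list CXCL8 rose while TNFAIP6 and VCAM1 fell. CXCL10, CXCL9, CXCL16, CCL4, CSF2, IL33, CD74, LGALS9, PTGES and PTGS2 were named after their values were seen.

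**Figure D2:**
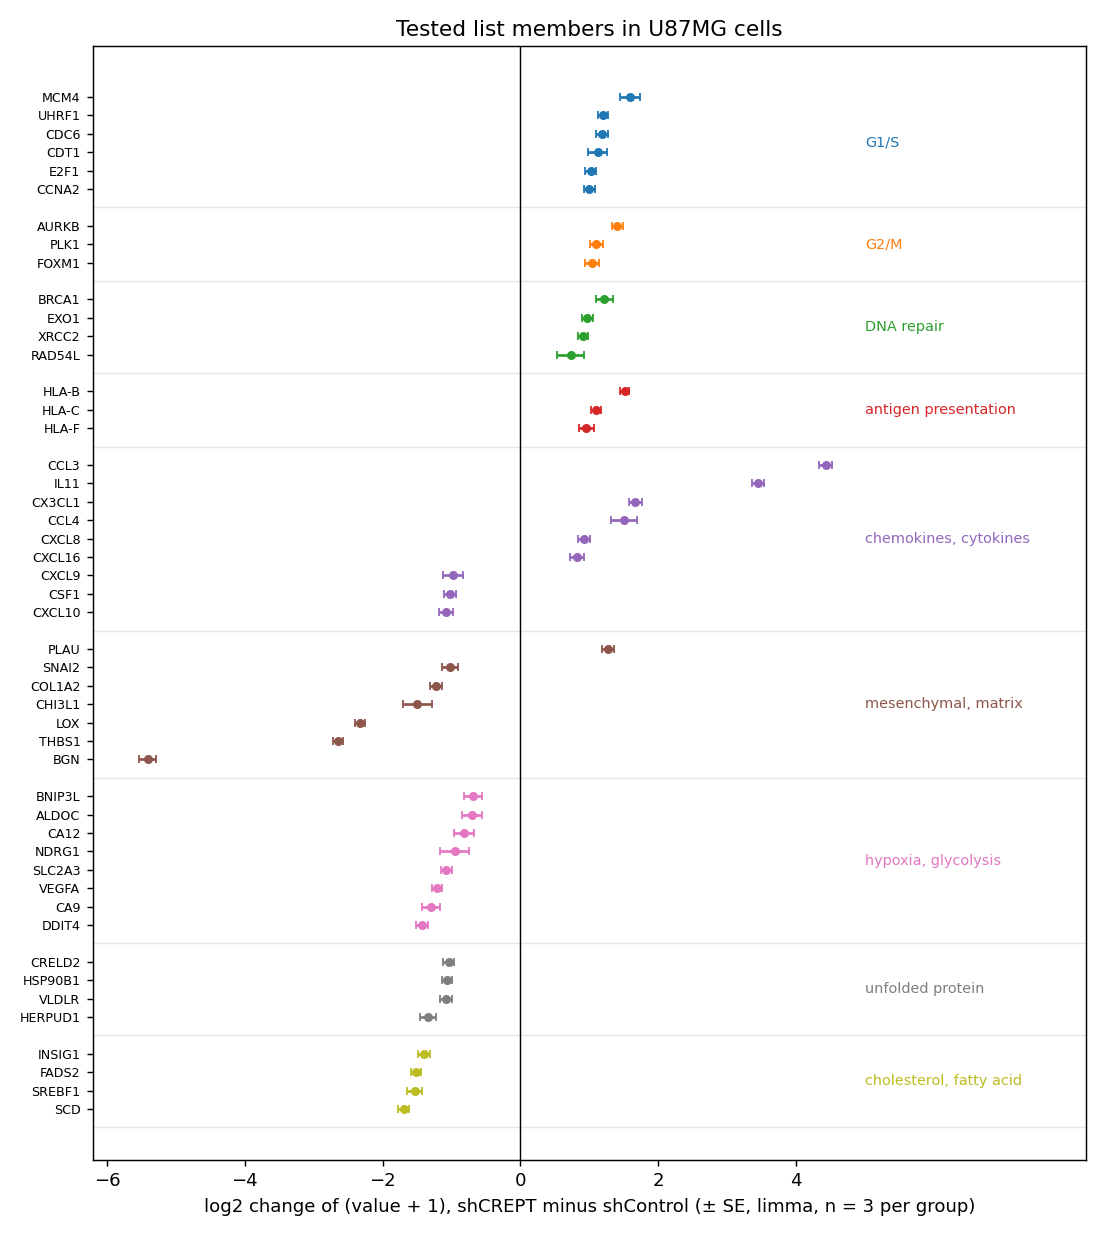
Log2 change of (value + 1), shCREPT minus shControl, with its standard error from limma (n = 3 per group), for the 48 tested members of 9 fixed lists, grouped and coloured by list. All points of the G1/S, G2/M, DNA repair and antigen presentation lists (tested members alone) lie above 0. All points of the hypoxia, unfolded protein and lipid lists lie below 0. BNIP3L is drawn below 0 too, and it turned sign under median-of-ratios rescaling, which is not drawn. The cytokine list runs from −1.08 for CXCL10 to 4.43 for CCL3.

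Of 41 mesenchymal and matrix genes, 9 had a row and 7 were tested: BGN, THBS1, LOX, COL1A2, CHI3L1 and SNAI2 fell and the protease PLAU rose 2.41-fold (camera adjusted p = 0.0819 for the list). Of the untested members, COL3A1 is down and MMP1 up in the authors' deposited table, with log2 fold changes of −3.50 and 2.41. THBS1 fell from 168 ± 6.87 to 25.9 ± 0.648, LOX, which crosslinks collagen, from 88.2 ± 3.38 to 16.8 ± 0.414, and COL1A2 from 1093 ± 7.81 to 467 ± 31.8 (SD, n = 3). All 8 listed genes of the 32 for hypoxia and glycolysis fell, among them VEGFA (2.31-fold lower), the stress gene DDIT4 (2.70-fold lower) and the carbonic anhydrase CA9 (2.46-fold lower), and BNIP3L turned sign under median-of-ratios rescaling. Under that rescaling the log2 changes of VEGFA, DDIT4 and CA9 went from −1.21, −1.42 and −1.29 to −0.32, −0.54 and −0.42. The hypoxia list missed the threshold (camera adjusted p = 0.0648; adjusted p = 0.325 with an estimated correlation) and passed it with a pseudocount of 5, with no filter on low values and with the replicate number as a block. Of 27 genes of cholesterol and fatty acid synthesis, 23 have no row. The 4 listed fell, SCD 3.34-fold, FADS2 3.05-fold, INSIG1 3.0-fold and their regulator SREBF1 2.95-fold. Median-of-ratios rescaling moved their log2 changes from between −1.40 and −1.70 to between −0.62 and −0.83. Of 28 genes in the unfolded protein list, 24 have no row. The 4 listed, HSP90B1, CRELD2, VLDLR and HERPUD1, also fell, HSP90B1 from 1199 ± 25.7 to 574 ± 23.4. The falls of HSP90B1, CRELD2 and VLDLR kept their sign and lost their call under median-of-ratios rescaling. Neither list had enough tested members for a list test. From the YAP/TEAD list NT5E and F3 rose and ARHGEF17 and IGFBP3 fell, HEY1, the 1 tested gene of 2 listed from the stem cell list, fell 5.21-fold, and FSTL3, the 1 tested gene of 3 listed from the TGF-beta list, rose 1.91-fold. In the authors' deposited table the untested SALL2 and TAGLN are down and INHBA is up. PLAU, CHI3L1, SNAI2, COL3A1, MMP1, SALL2, TAGLN, INHBA and BNIP3L were named after their values were seen. Adjusted over the list alone, the counts of rises and falls in each of the 19 lists equalled those over all genes tested.

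Markers of other cell types gave few rows. None of 15 markers of microglia, macrophages and monocytes and none of 11 T cell markers has a row. Rows are limited to genes past the authors' threshold, so a missing row does not tell whether a marker is expressed. The astrocyte markers GFAP, S100B and SLC1A3 fell, as did the endothelial markers CDH5 (4.66-fold) and KDR (2.11-fold), the fibroblast marker COL1A2, the oligodendrocyte lineage receptor PDGFRA (5.55-fold) and the neuronal filament NEFL (4.57-fold). Of the epithelial markers, CLDN4 rose and KRT19 fell. The early response gene EGR1 was 2.41-fold lower. The mitochondrial ribosomal RNA MT-RNR1 was the highest listed gene in every library and moved with the groups, from 3200 ± 258 in shControl to 6466 ± 498 in shCREPT (SD, n = 3), a 2.02-fold rise, and the 10 highest genes took 27.6 to 29% of the listed sum in shControl and 36.1 to 37.4% in shCREPT. The other 10 mitochondrial transcripts of that list have no row. Under quantile normalization MT-RNR1 had a log2 change of 0 because it ranked first in each library, and under median-of-ratios rescaling KDR, SLC1A3, EGR1 and IGFBP3 kept their sign and lost their call.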

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

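Fisher's exact test of the directions in the authors' deposited table and the count of splits were chosen after the data were seen; the other settings were fixed before the data were examined. The 78 genes named by rule kept their direction and call under all settings that tested them, except 8 that lost the call under median-of-ratios rescaling and MT-RNR1 under quantile normalization; BNIP3L, named outside the rule, turned sign under that rescaling. A pseudocount of 5 gave 120 genes up and 187 down by 1 or more (log2), since it shrinks low genes by construction. The stricter filter left 487 genes to test and called 485, 214 up and 271 down (175 and 229 by 1 or more). Rescaling by median of ratios, whose factors follow the down majority of the table, called 371 down (476 up and 92 down by 1 or more), and quantile normalization called 486 up and 632 down (416 up and 276 down by 1 or more, so the majority turned in that subset alone). Leaving out 1 library at a time gave 1137 to 1152 changed genes and changed no list call. Of the 5 lists, 1 passed in the main test, and 2 passed with a pseudocount of 5, no filter or the replicate block, each adding hypoxia (adjusted p = 0.0478, 0.0371 and 0.0485, direction down; 7.22e-05 to 0.325 over its alternatives; the cause was not tested). With an estimated correlation 0 passed (0.253 for G1/S), and all 5 passed fry, which does not compare a list with other genes (5.42e-06 for cytokines, 0.00113 for immunosuppressive genes, 3.04e-06 for matrix genes down, 7.22e-05 for hypoxia down). Every tested member had been selected for a difference between the groups, so a pass by fry was largely fixed and is no support for a list. Fisher's test gave 0.0212 for G1/S. Same-numbered libraries did not deviate together (r = −0.109, 0.018 and −0.179), and libraries of other numbers gave r of −0.112 to 0.199. No sign of pairing was seen, but these few values have no null to set them against and cannot exclude it. The fit with the replicate block called 1156 genes. Of the 10 splits of the libraries, 1, the real one, gave as many genes as its 1159, and the highest other gave 1. Every listed gene had been selected for the real split, so this contrast was fixed in advance and decides nothing about the grouping. The 10 splits are also too few for a share under 0.05. Depth is unknown and sets no bound here. The count test was not run for want of counts, and RPRD1B and the marker lists gave no value to vary.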

Other observations

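The tests of gene families, of chromosomes, of a local cluster or shared reads, of the density of down genes, of distance from the authors' threshold and of the cell cycle and DNA repair genes were chosen only after the result was seen. Gene names that begin with CDC and a digit, or with E2F, MCM, ORC, CHAF, CENP, SKA or KIF, made up 16 listed genes. All were up in the authors' deposited table and higher in the limma fit, such as CDC25A (3.02-fold), MCM10 (2.85-fold) and E2F7 (2.19-fold). The two-sided Fisher's exact test of their directions against the rest of the table gave an adjusted p of 6.09e-06 over 14 families. These prefixes were pooled after the result was seen, and that p does not count the choice. The set also holds E2F1, CDC6 and MCM4 of the G1/S list, so it is no independent support. In CENPS-CORT, another member, the groups overlapped. Zinc finger genes named ZNF were listed 20 up and 8 down (adjusted p = 0.00952), among them ZNF107 (2.76-fold) and ZNF93 (2.33-fold), and these paralogs can share reads. Several of those up lie close together on chromosomes 7 and 19, and Fisher's exact test counts neighbours as independent. The 14 on chromosome 19 were listed 9 up and 5 down (Fisher's exact test, adjusted p = 0.195). Of the 18 ZNF genes that passed in the limma fit, 1 turned sign under median-of-ratios rescaling. Complement genes fell, all 7 of those listed, with CFB going from 215 ± 3.92 to 41.5 ± 1.33 and CFI from 118 ± 2.13 to 34.4 ± 2.82 (SD, n = 3); the family missed the threshold (adjusted p = 0.195), and C4A and C4B are near-identical. Of 13 clustered protocadherins, 11 were down in the authors' deposited table (adjusted p = 0.195), and 1 of the 7 falls that passed in the limma fit turned sign under median-of-ratios rescaling. LOX, LOXL1, LOXL3 and LOXL4 were all down in the authors' deposited table (adjusted p = 0.268), LOXL1 from 193 ± 9.12 to 56.6 ± 1.43 (SD, n = 3). In the authors' deposited table, p-values and adjusted p-values fit a ranking over 21011 tested genes, in which the last listed gene ranks 8155; 6525 of the genes ranked up to it have no row.

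Genes on chromosome 17 went against the table's trend: 85 were up and 33 down (72.0% up), against 37.5% up on the other chromosomes, with an adjusted p of 7.91e-12 over 23 chromosomes by two-sided Fisher's exact test, and no other chromosome passed. A single local cluster is argued against, since the excess held without the 10 Mb window with the most up genes (30 to 40 Mb). Reads shared between overlapping listed genes, or within the CCL3, CCL4 and TBC1D3 families, are argued against too. The excess held among protein-coding genes without these (the larger of the 2 two-sided Fisher's exact p-values was 1.33e-09). Reads shared with genes that have no row, or within other families, were not tested. GC content is argued against, since permuting directions within 10 classes of transcript GC gave a mean of 50.4 up genes and at most 74 (permutation p = 1e-05, the smallest they can give). More copies of chromosome 17, whole or in part, in the shCREPT cells than in the shControl cells is a candidate explanation. These relative values cannot tell a gain in shCREPT from a loss in shControl. Of 9 windows of 10 Mb with 5 or more listed genes, 8 exceeded the other chromosomes' up share by over 1 percentage point (53.8% or more). The excess was largest from 0 to 50 Mb, where each window was 70.8% to 85.7% up. The windows from 50 to 90 Mb were 37.5%, 66.7%, 53.8% and 66.7% up, on 6 to 13 listed genes each. The window from 50 to 60 Mb, with 3 up and 5 down (37.5% up), showed no excess. Down genes were 2.19% of the annotated protein-coding genes of chromosome 17 against 3.69% elsewhere (Fisher's exact p = 0.00608). The up genes of chromosome 17 also lay nearer the authors' threshold, 60.0% of them under 1.5 (log2) against 47.6% of other up genes (exact p = 0.0359). Their median log2 fold change in the authors' deposited table was 1.32, against 1.53 for other up genes. Whether a copy difference gives changes of that size was not tested. DNA copy number was not analysed here, and an effect of the knockdown on these genes stays open and untested.

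All 13 listed genes of the G1/S, G2/M and DNA repair lists were higher in shCREPT, whereas the series title links CREPT to the promotion of proliferation. The 3 members on chromosome 17 (CDC6, AURKB and BRCA1) do not carry this, since the other 10 were all up against 37.4% up in the rest of the table (two-sided Fisher's exact p = 5.72e-05 without chromosome 17). The scaling of the libraries stays open. Under median-of-ratios rescaling and quantile normalization 13 of 13 stayed higher, with smallest log2 changes of 1.57 and 0.91. The rescaling raises every gene in shCREPT, so its outcome was fixed. Quantile normalization moved the typical listed gene up but lowered some rises outside these lists, such as HLA-C (log2 change from 1.10 to 0.99). The members of these lists named by rule all moved further up, such as UHRF1 (1.20 to 1.41) and RAD54L (0.73 to 0.91). Its outcome was therefore largely fixed for them too. Both rest on the selected genes alone and cannot show how the whole libraries should be scaled. The selection of the table stays open too: 74 of the 87 fixed members have no row, and the table does not say whether those moved the same way. An effect of the hairpin itself, which the design names, stays open as well.

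Whether long genes lose more transcript in shCREPT cells was tested over the 1221 listed protein-coding genes, across genes that are not independent replicates. Spearman's rho of the authors' log2 fold change and gene span was −0.029 (permutation p = 0.315) and Pearson's r with log10 span was −0.053 (permutation p = 0.0653; −0.054 without the 2 genes farthest from the median span), so no relation passed. The median span was 33.4 kb for up genes and 33.9 kb for down genes.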
